A study of Homo sapiens with 12 samples.

How the data were processed

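RNA from 12 T cell samples of 3 blood donors was measured on Affymetrix HG-Focus arrays, 1 array per sample, per the file headers of the instrument settings. The labels name the donor of each sample, so the 3 arrays of a group come from separate donors, and each donor has 1 array in each of the 4 groups. The deposited value table holds a linear signal intensity for 8793 probe sets on each array. The method that summarised the probes of a set is not given in the sources used here, and no detection calls were used. Each array of the deposited table has a median of exactly 1, from which a division of the deposited intensity by the array median was inferred. On every array at least 99.98% of the low values were whole multiples of 0.1 over a constant (within 0.01 of a step), and that constant gives the median intensity before scaling, from 3.3 to 15.7 signal units. No column was a copy of another. The instrument files gave the array lot, the fluidics module and the hybridisation day, which served only as batches: 2 arrays (both 1g arrays of donor 2) came from a smaller lot and 10 from a larger one, and 8 arrays were hybridised on a first day (donors 2 and 4) and 4 on a second (donor 5). Within each donor the 4 groups were on different fluidics modules, and on the first day each group had a module of its own.

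Genes were named from the platform annotation supplied with the table, through Entrez identifiers and a RefSeq gene table (GRCh38.p14), used for names alone. Of the probe sets, 7840 had 1 gene, 388 several, 518 no name and 47 were controls, and 7838 matched a current symbol. Probe sets with several genes or none, controls, and genes of the Y chromosome and XIST were left out, which left 7827. A probe set was kept when it exceeded the 40th percentile of the array on at least 3 arrays, which kept 5963 probe sets of 5870 genes. A gene with several took its brightest. Since the medians were equal, the deposited scale was kept as normalized. The distributions were not equal: the upper quartile over the median was 2.21 ± 0.20 (SD, n = 3) in vg 4 hr. It was 2.78 ± 0.19 in 1g 0 hr, 2.73 ± 0.48 in 1g 4 hr and 2.67 ± 0.35 in vg 0 hr. A floor of 0.25 of the array median was set and log2 taken, which put 9.2% of the values at the floor. A floor of 16 had been planned for signals on the usual scale of this platform. The table was in units of the array median instead, so 0.25 was set before any test was run, with 4-fold higher and lower floors as alternatives in place of 64 and 4. A fold against a group at the floor on all 3 arrays is a lower bound, and such genes were not ranked by size. A fold is on the floored scale and understates the change of a gene near the floor.

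Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) on all 12 arrays with the 4 groups as terms, which leaves 8 residual degrees of freedom. The comparisons were activation at 1g, activation in vg, vg against 1g at 0 hr and at 4 hr, and the difference between the 2 activation responses. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists (23 pathway and 7 cell type marker lists, 30 in all) were fixed before the data were examined, as were the comparisons and most of the other settings tried. They were tested against all other genes with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 150 tests. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of that list. The mean response of 92 measured of 113 listed genes in 5 activation lists (surface molecules, cytokines, chemokines, NF-kappaB, immediate early genes) was taken per donor and tested by an exact sign flip.

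The genes named were, for each comparison, the 12 largest rises and 10 largest falls among genes called and changed the same way in all 3 donors. Where fewer than 5 were called, the 10 genes with the smallest p were named. Added to these were up to 4 members of a list by smallest p, and IL2, IL2RA, IFNG, TNF, CD69, MYC, REL, EGR1, FOS and CREM in every comparison.

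Same-numbered samples come from the same donor per the labels. Deviations from the group means correlated at 0.09 on average over 18 pairs of arrays of the same donor (from -0.10 to 0.25), and at -0.05 over 36 pairs of different donors. The donor block was an alternative to the fit without it, so the main counts do not use the pairing of arrays by donor. Other settings fixed beforehand were the normalization, the filter, the floor, the variance trend, the mean of a gene's probe sets, the array lot and hybridisation day as terms, the larger lot alone, only the groups compared, a fold minimum of 2, and leaving out each donor and each array. Added after the data were seen were array brightness as a term, the 3' to 5' gap of GAPDH as a term, array quality weights with and without the block, and a fit without the 2 dimmest arrays outside vg 4 hr (1g 4 hr replicate 4 and vg 0 hr replicate 2).

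The code was tested on simulated data for 5870 genes with the observed means and spread and 200 changed genes. The changed genes were drawn only from those with a mean well above the floor, so the shares recovered do not hold for weak genes. For activation at 1g, 6% of 2-fold, 50.7% of 4-fold and 100% of 16-fold changes were recovered, and for vg at 4 hr 3%, 52.2% and 100%. For the difference of the activation response the shares were 0%, 32.8% and 92.4%. From 2 to 9 unchanged genes were called per comparison. The list test recovered the 1 list that was moved and called 0 others. The noise was drawn independently for each gene, so this does not measure false calls where the genes of a list correlate. In the data the estimated correlation reached 0.467 (cAMP-responsive CREB targets). The simulation of comparisons that share groups used 100 draws. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.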

Results

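Gene expression was measured in human T cells from buffy coats of 3 blood donors, cultured at normal gravity (1g) or on a random positioning machine (vg), which turned the cultures at 60 degrees per second so that no direction stays down. T cells had been enriched by negative selection. Activation was with concanavalin A, a lectin that crosslinks the T cell receptor complex, plus an antibody against CD28, the main costimulatory receptor. The 12 Affymetrix HG-Focus arrays formed 4 groups of 3: unactivated cells at 1g (1g 0 hr), cells activated for 4 hours at 1g (1g 4 hr), and the same time points in vg (vg 0 hr and vg 4 hr). Cells in vg had spent 2 hours on the machine before collection or activation. No matching time in culture was recorded for the 1g cells, so the vg 0 hr and 1g 0 hr groups may also differ by that culture step. Levels were signals divided by the array median, and changes are on the log2 scale with the fitted standard error (SE), n = 3 arrays per group. With 3 arrays per group, the median SE of a change between groups was 0.68. Brightness differed between arrays. The median signal before scaling was 7.90 ± 1.40 (SD, n = 3) in 1g 0 hr, 9.13 ± 6.23 in 1g 4 hr, 9.97 ± 5.70 in vg 0 hr and 5.07 ± 0.85 in vg 4 hr. The log2 gap between the 3' and 5' probe sets of GAPDH, a sign of RNA integrity, was 1.38 ± 0.23, 0.63 ± 0.34, 1.44 ± 0.83 and 1.17 ± 0.41 in these groups, and that of ACTB was 0.71 ± 0.67, 0.69 ± 0.74, 0.55 ± 0.88 and -0.22 ± 1.67.

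The first comparison asked what activation did at normal gravity. Cytokine and chemokine genes were among those that rose: IFNG, the gene of interferon gamma, rose 62.8-fold (log2 5.97, SE 0.71, limma adjusted p = 0.00062), LTA (lymphotoxin alpha) 55.0-fold, CCL20 50.4-fold, TNF 24.9-fold and CCL4 23.5-fold. IL2, the T cell growth factor, was at the floor on all 3 unactivated 1g arrays and rose at least 17.5-fold, and the chemokine XCL1 rose at least 11.3-fold for the same reason. CRTAM, a surface receptor of activated lymphocytes, rose 24.8-fold, the transcription factor EGR3 17.0-fold, the apoptosis-related IER3 11.6-fold, the MAP kinase phosphatase DUSP5 11.2-fold and the RNA polymerase I subunit POLR1G 8.48-fold. TRAF1, a signalling adaptor of TNF receptors, rose 5.60-fold, the nucleoside diphosphate kinase NME1 5.18-fold and NFKB1, a subunit of NF-kappaB, 4.89-fold. These were all 15 genes called among 5870 tested, with 15 higher and 0 lower, and each moved the same way in all 3 donors. LTA, CRTAM, EGR3 and POLR1G were at the floor on 2 of the 3 unactivated 1g arrays and CCL20 on 1, so their folds are understated. Of the other genes set for every comparison, IL2RA (log2 3.20, limma adjusted p = 0.092), CD69 (3.36, 0.31), EGR1 (2.36, 0.33), MYC (2.58, 0.37), FOS (2.10, 0.83), CREM (0.35, 0.97) and REL (-0.10, 0.99) did not pass.

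**Figure D1:**
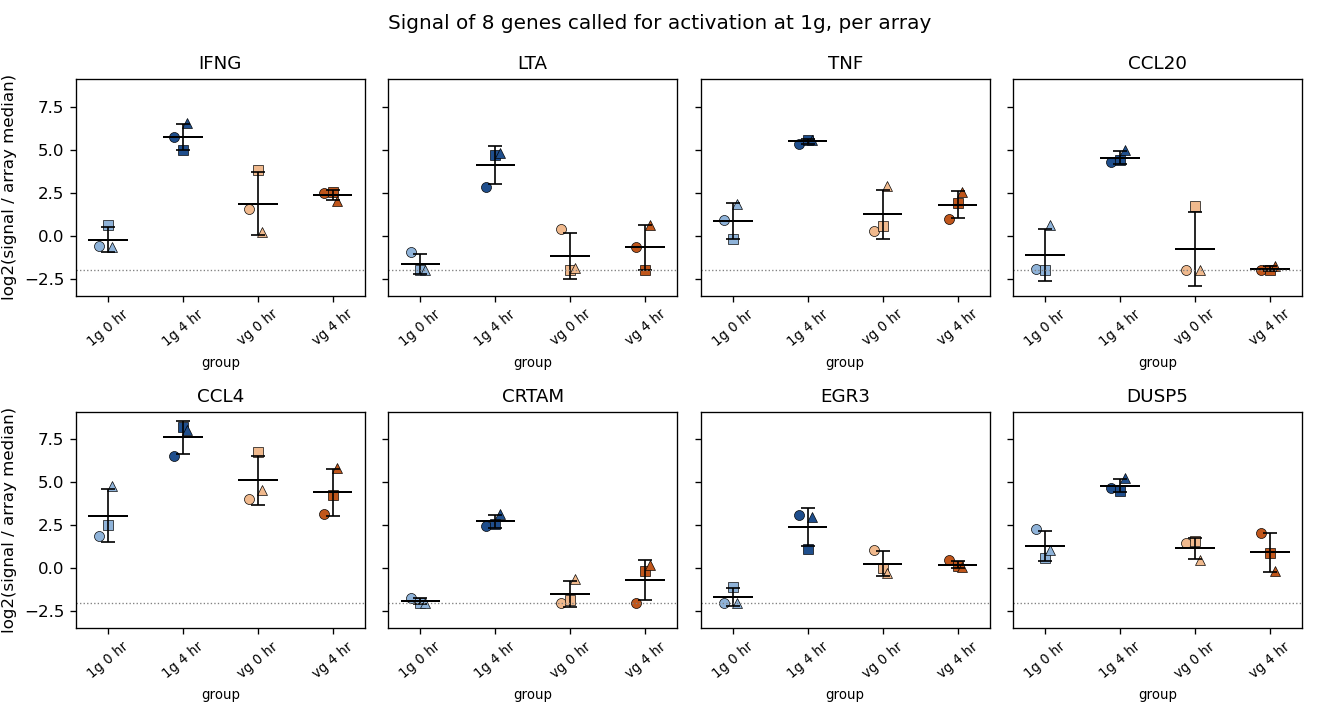
Log2 signal over the array median (vertical axis) of 8 genes that rose with activation at 1g, per array and group, with circles for replicate 2, squares for replicate 4 and triangles for replicate 5. Black lines are the group mean ± SD (n = 3) and the dotted line is the floor of 0.25. The 3 arrays of 1g 4 hr lie above every vg 4 hr array in each of the 8 panels. The genes were chosen for their rise at 1g, which favours such a gap.

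By gene list, cytokines rose together at 1g (16 measured, median log2 1.68, camera adjusted p = 6.65e-13, 0.00448 with an estimated correlation). Of these, 4 passed the test over all genes and 8 were higher with p adjusted over the list alone: IL2, IFNG, TNF, LTA, IL4, IL13, LIF and TNFSF14. T cell activation surface molecules also rose together (17 measured, median 0.62, adjusted p = 5.62e-05, and 0.0423 with an estimated correlation), with 0 over all genes and 5 adjusted over the list alone, among them CTLA4 (log2 2.71) and TNFRSF9 (2.75, limma adjusted p = 0.0573, and 0.0260 with the donors as a block). Another 9 lists rose at the preset correlation only. They were the aminoacyl-tRNA synthetases (14 of 15 above 0, median 1.19, adjusted p = 0.123 with an estimated correlation), NF-kappaB family and targets (0.96, 0.127), chemokines (0.87, 0.206), immediate early genes (0.99, 0.631), ribosome biogenesis (1.34, 0.129), apoptosis regulators (0.87, 0.206), endoplasmic reticulum stress and amino acid response (0.37, 0.486), proteasome subunits (0.63, 0.732) and cAMP-responsive CREB targets (0.69, 0.769), each given as median log2 and adjusted p with an estimated correlation. Over all genes, 3 of the NF-kappaB list, 3 chemokines, 2 immediate early genes and 0 of the other lists passed. Adjusted over the list alone these were 5, 5 and 6, with 4 aminoacyl-tRNA synthetases, 4 ribosome biogenesis genes, 2 stress genes (SLC7A5 and SLC3A2) and 1 apoptosis regulator (BCL2A1). CREB targets did not pass in 9 of 34 other settings. The proteasome, apoptosis and stress lists did not pass in the larger lot, without donor 2 or without 1g 4 hr replicate 2. Ribosomal proteins fell as a list, with 20 of 20 below 0 and a median of -0.66 (adjusted p = 0.000549, and 0.725 with an estimated correlation). The list did not pass with the GAPDH gap as a term, with quantile normalization or without donor 4. KLF2, a quiescence factor of resting T cells, was at -2.49 (limma adjusted p = 0.0573) and was lower only with p adjusted over the list alone. The GAPDH gap was smaller on the activated arrays (0.63 ± 0.34 against 1.38 ± 0.23), and with it as a term, added after the data were seen, 5 genes were called (IFNG, LTA, IL2, EGR3 and CRTAM). The 10 that lost the call had a median log2 of 3.35 (median SE 0.73) with the term and 3.49 (0.60) without it. The count of 15 was 19 with the array lot as a term and 5 within the larger lot, and 19 with the hybridisation day as a term and 4 within the first day. Without 1g 0 hr replicate 4 or 1g 4 hr replicate 5 it was 5, and without donor 2, 4 or 5 it was 1, 1 or 4.

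In vg, the cytokine genes that rose at 1g did not pass the test of activation: IFNG was at log2 0.50 (SE 0.71), TNF at 0.55 (0.67), IL2 at 0.75 (0.77) and LTA at 0.49 (0.80). No gene was called among 5870 (0 at limma adjusted p under 0.05, with 430 at an unadjusted p under 0.05, 84 higher and 346 lower, where chance alone gives 294). The 10 genes with the smallest p were named although none passed. RXRA, a retinoid receptor, was at log2 -3.49 (SE 0.58, limma adjusted p = 0.055), OAZ2, an inhibitor of polyamine synthesis, at -3.25 (0.22) and the spindle checkpoint protein BUB3 at -3.24 (0.56). RHOC (-2.16), IL21R (-2.53), MBNL1 (-2.65), SETDB1 (-2.13), SHOC2 (-2.02), TFR2 (2.44) and EXO1 (2.19) all had an adjusted p of 0.64. With the donors as a block, RXRA alone was called (limma adjusted p = 0.0353). IL2RA was at -0.43, CD69 at -0.02, EGR1 at 1.04, MYC at 0.45, FOS at -0.43, CREM at -0.34 and REL at 0.16.

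Of the gene lists in vg, resting T cell genes fell as a list after activation (14 of 14 below 0, median -0.80, camera adjusted p = 0.00756, and 0.496 with an estimated correlation). They included KLF3 (-1.65), TOB1 (-1.94), CXCR4 (-1.97) and BTG1 (-1.46), none past the test alone. The cAMP and protein kinase A components also fell as a list (16 of 17 below 0, median -0.59, adjusted p = 0.0142, and 0.41 with an estimated correlation), with ADCY7 at -2.05 and AKAP8 at -2.12. With donors as a block, heat shock proteins and chaperones passed as well (9 of 16 above 0, median 0.10, adjusted p = 0.0388 against 0.0685 without the block). The adjusted p of that list was 0.769 with an estimated correlation, without the block. The list of cytokines did not pass in vg (median 0.18, adjusted p = 0.105). In this comparison the median over all genes was -0.24, so the lists moved against a background below 0. The counts of called genes were 0 with the array lot as a term and within the larger lot, 1 with the hybridisation day as a term and 0 within the first day. The brightness of the vg 4 hr arrays, 5.07 ± 0.85 against 9.97 ± 5.70 in vg 0 hr, moved with this comparison, and with brightness as a term neither list passed. Without donor 4 neither passed, resting T cell genes did not pass without donor 5 or vg 4 hr replicate 5, or with quantile normalization, and the cAMP and protein kinase A components did not pass without vg 0 hr replicate 4 or with the 60th percentile filter.

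Unactivated cells in vg and at 1g were compared next. Immediate early genes, transcribed within minutes of a stimulus, rose as a list (28 measured, 18 above 0, median 0.47, camera adjusted p = 0.00303, and 0.769 with an estimated correlation), as did cAMP-responsive CREB targets (15 of 17 above 0, median 0.52, adjusted p = 0.00671, and 0.769 with an estimated correlation). They included NR4A3 (1.05), NR4A2 (1.47), ATF3 (0.91) and EGR4 (1.46). The mean shift of both lists together lay in 1 donor: it was -0.06, 1.37 and 0.12 in donors 2, 4 and 5, and the median over their 36 genes was 0.04 without vg 0 hr replicate 4 against 0.47 with all arrays. Cytoskeleton and adhesion genes fell as a list (20 of 25 below 0, median -0.38, adjusted p = 0.0195, and 0.769 with an estimated correlation), with profilin PFN1 at -1.23 and the integrin ITGA4 at -1.04. No gene was called (0 of 5870 with limma, and 117 at an unadjusted p under 0.05 against 294 by chance). All adjusted p were 1, including those of LAPTM4B (log2 -2.56), SNRPC (2.25), PSG2 (2.12), HOXC11 (-2.15), PRG3 (-1.92), EGR3 (1.96), LZTR1 (-1.79), KLK12 (1.85), FOXH1 (-1.82) and PERP (2.10), the 10 genes with the smallest p. IFNG was at 2.07, IL2RA at 1.15, FOS at 1.79, IL2 at 0.66, CD69 at 0.68, TNF at 0.39, CREM at 0.37, MYC at -0.16, REL at -0.03 and EGR1 at 0.01. The 3 vg 0 hr arrays were washed on a fluidics module that held no other group, so module and group cannot be told apart. Counts within the first day carry this limit in every comparison, since each group then had its own module. With the array lot as a term the count stayed 0, as it did within the larger lot, and with the hybridisation day as a term or within the first day. Of the 3 lists, 0 passed without donor 4, without vg 0 hr replicate 2, vg 0 hr replicate 4 or 1g 0 hr replicate 5, or without the 2 dimmest arrays outside vg 4 hr, and cytoskeleton and adhesion genes did not pass in 10 of 34 other settings. In the larger lot all 3 passed.

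After 4 hours of activation, cells in vg had lower levels than cells at 1g of several genes that activation raised at 1g. CCL20 fell 88.1-fold (log2 -6.46, SE 0.88, limma adjusted p = 0.00428), LTA 28.2-fold, IL21R (the interleukin 21 receptor) 17.4-fold, DUSP5 14.7-fold, TNF 13.0-fold, IER3 11.2-fold, XCL1 11.1-fold, IFNG 10.6-fold and CRTAM 10.5-fold. EZH2, a histone methyltransferase, fell 8.73-fold. TNFRSF9, a costimulatory receptor, fell 8.38-fold, the amino acid transporter SLC7A5 fell 5.65-fold and TRAF1 fell 5.23-fold. In all, 21 genes were lower and 0 higher, each in the same direction in 3 of 3 donors, and 10 of the 15 genes called for activation at 1g were among them, NME1 included. All 15 were below 0. Both comparisons use the 1g 4 hr arrays, so genes picked for high values there are favoured to lie lower in vg. CCL20, XCL1, IL21R and EZH2 were at the floor on 2 of the 3 vg 4 hr arrays and LTA and CRTAM on 1, so these falls are understated. IL2 (log2 -2.72, limma adjusted p = 0.13), IL2RA (-2.48, 0.15), MYC (-2.29, 0.21), CD69 (-2.70, 0.23), EGR1 (-1.32, 0.44), FOS (-0.74, 0.89), CREM (-0.32, 0.92) and REL (0.23, 0.94) did not pass.

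Across lists, 11 fell in vg at 4 hr at the preset correlation, and cytokines fell at the estimated one as well (15 of 16 below 0, median -1.40, camera adjusted p = 4.99e-06, 0.0279 with an estimated correlation). All 24 proteasome subunits were below 0 (median -1.08, adjusted p = 1.8e-06, and 0.41 with an estimated correlation), with PSMB5 at -2.53 and PSMB2 at -2.72, and 6 were lower adjusted over the list alone. All 15 aminoacyl-tRNA synthetases were below 0 (median -1.52, adjusted p = 2.16e-06, and 0.129 with an estimated correlation), with GARS1 at -1.94, WARS1 at -2.56 and 9 lower adjusted over the list alone. Glycolysis fell as a list (17 of 19 below 0, median -1.25, adjusted p = 0.000581, and 0.41 with an estimated correlation), with hexokinases HK2 at -2.96 and HK1 at -2.44. Ribosome biogenesis had a median of -1.41 (adjusted p = 0.000402, and 0.212 with an estimated correlation), with PES1 at -3.30 and BYSL at -2.76. The other lists past the preset test were NF-kappaB family and targets (median -1.02, adjusted p = 0.206 with an estimated correlation), chemokines (-1.10, 0.38), T cell activation surface molecules (-1.07, 0.0872), endoplasmic reticulum stress and amino acid response (-0.99, 0.486), immediate early genes (-0.79, 0.769) and apoptosis regulators (-1.03, 0.41, with BCL2 at -3.15). Over all genes, 3 cytokines, 2 NF-kappaB genes, 2 chemokines, 1 surface molecule, 1 stress gene and 1 immediate early gene fell. Adjusted over the list alone these were 6, 7, 6, 7, 5 and 4, with 8 glycolysis genes, 7 ribosome biogenesis genes and 2 apoptosis regulators. Immediate early genes did not pass in 11 of 34 other settings, apoptosis regulators in 9 and endoplasmic reticulum stress and amino acid response in 4. The median change of all genes was -0.19, and 0.01 with quantile normalization, so the counts of genes below 0 include a background below 0.

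Lists that did not pass in vg at 4 hr included T cell receptor signalling components (16 of 24 below 0, median -0.62, camera adjusted p = 0.236), JAK-STAT and SOCS (-0.48, 0.118), G1 to S phase genes (-0.48, 0.181), interferon-induced genes (-0.54, 0.25), NFAT and calcineurin (-0.63, 0.402), protein kinase C and MAP kinase pathways (-0.20, 0.652) and heat shock proteins and chaperones (-0.29, 0.803, where the mean was -0.07 and the test pointed up). Markers of other blood cells did not pass either: monocyte (median 0.13, adjusted p = 0.0954), erythroid (0.88, 0.195), platelet (0.40, 0.327), dendritic cell (0.61, 0.38, with 2 genes), B cell (0.04, 0.843) and neutrophil markers (-0.27, 0.922). Natural killer cell markers, several of which cytotoxic T cells share, had a median of -1.02 (camera adjusted p = 0.126). They passed with donors as a block (0.0173), where the adjusted p was 0.76 with an estimated correlation and no block. GZMB was at -2.72 and KLRD1 at -2.76 (0.258, and 0.0451 with the block). These markers were already lower in vg at 0 hr, with 11 of 11 below 0 (median -0.32, camera adjusted p = 0.177, and 0.0505 with the block).

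The vg 4 hr arrays were dim (median signal 5.07 ± 0.85 against 9.13 ± 6.23 in 1g 4 hr), and with brightness as a term, added after the data were seen, 12 genes were lower. The mean over the 92 genes of the activation lists was -1.14 with the term and -1.28 without it. The GAPDH gap was 1.17 ± 0.41 in vg 4 hr against 0.63 ± 0.34 in 1g 4 hr, and with it as a term, also added after the data were seen, 3 genes were lower (CCL20, IL21R and LTA). The 18 that lost the call had a median log2 of -2.96 (median SE 0.64) with the term and -3.06 (0.59) without it. With the donors as a block 53 genes were lower, including all 21, and of the genes named here as not past, PSMB5, PSMB2, GARS1, WARS1, HK2, BYSL, PES1 and BCL2 then passed (limma adjusted p from 0.0167 for WARS1 to 0.0464 for PSMB2 and PES1). The array lot as a term gave 13 and the larger lot alone 3, and the hybridisation day as a term gave 49 and the first day alone 16. With quantile normalization 7 genes were lower. Single arrays moved the count: it was 0 without 1g 4 hr replicate 5, 1 without vg 4 hr replicate 4, 5 without 1g 4 hr replicate 4, 7 without 1g 4 hr replicate 2, 11 without vg 4 hr replicate 2, 12 without 1g 0 hr replicate 4 and 122 without vg 4 hr replicate 5. Without donor 2 or 4 it was 0.

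The last comparison tested whether the activation response itself differed between vg and 1g. The genes with the smallest p, none past the test, were CCL20 (log2 -6.81, SE 1.25) and IFNG (-5.47, SE 1.01), both with a limma adjusted p of 0.0994, then, by p, IL21R (-4.64, 0.105), LTA (-5.30, 0.206), XCL1 (-3.80, 0.206), EGR3 (-4.14, 0.206), CCL4 (-5.25, 0.206), POLR1G (-3.60, 0.206), DUSP5 (-3.73, 0.218) and SLC7A5 (-2.82, 0.218). No gene passed (0 of 5870, and 376 at an unadjusted p under 0.05, 287 of them lower, where chance alone gives 294). With the donors as a block 0 passed as well, and CCL20, IFNG, IL21R and CCL4 had a limma adjusted p of 0.0571. All 15 genes called for activation at 1g had a smaller change in vg at an unadjusted p under 0.05, with a median log2 change of 4.09 at 1g and 0.10 in vg. That set was chosen for its rise at 1g, which favours a smaller value in vg. TNF was at -4.09 (0.218), IL2RA at -3.62, IL2 at -3.37, CD69 at -3.37, MYC at -2.13, EGR1 at -1.32, FOS at -2.53, CREM at -0.69 and REL at 0.26. Higher vg values at 0 hr were part of the difference for IFNG (log2 2.07) and EGR3 (1.96), neither past the test at 0 hr, and less so for TNF (0.39). Of 5 genes responsive on the mean of both cultures, CRTAM, IFNG, LTA, TNF and OAZ2, 4 (80%) had a smaller response in vg, and OAZ2 was the exception. The share rests on these 5 genes, and with the block and array quality weights it was 48.3% (28 of 58 genes).

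Across the 92 measured genes of 5 activation lists fixed beforehand, the mean response was 1.30 ± 0.27 (SD, n = 3 donors) at 1g and -0.20 ± 0.29 in vg. The difference was -1.50 ± 0.06, with -1.57, -1.49 and -1.45 in donors 2, 4 and 5 (two-sided exact sign-flip p = 0.25, the smallest that 3 donors allow). In the donors whose 4 arrays came from 1 lot it was -1.47. A fit of the lists' mean over all 12 arrays gave this difference a wider SE of 0.33. At 4 hr alone, vg minus 1g was -1.655, -0.898 and -1.299 in donors 2, 4 and 5. The difference of the response also holds vg minus 1g at 0 hr, so the close values of the 3 donors rest on unlike parts. In donor 4 a part came from higher vg values at 0 hr, where immediate early genes were at 1.27. In donors 2 and 5 these genes were at -0.03 and 0.18. Among the lists, 10 had a lower response in vg: cytokines (median difference -1.35, camera adjusted p = 4.99e-06, 0.0279 with an estimated correlation), and, losing the call with an estimated correlation, aminoacyl-tRNA synthetases (-1.76, adjusted p = 0.148 with an estimated correlation), immediate early genes (-1.32, 0.725), chemokines (-1.50, 0.38), T cell activation surface molecules (-1.37, 0.0639), ribosome biogenesis (-1.80, 0.212), proteasome subunits (-1.02, 0.725), NF-kappaB family and targets (-1.12, 0.332), apoptosis regulators (-1.02, 0.41) and endoplasmic reticulum stress and amino acid response (-0.93, 0.732). The last did not pass in 16 of 33 other settings, apoptosis regulators in 12 and proteasome subunits in 1. In vg itself the median change was 0.18 for cytokines, 0.13 for the NF-kappaB list and below 0 for the others, against -0.24 for all genes. The endoplasmic reticulum stress list went from 0.37 at 1g to -0.37 in vg, a turn in direction and not a smaller change. With donors as a block endoplasmic reticulum stress and amino acid response did not pass (adjusted p = 0.0505) and glycolysis did (0.0487, against an adjusted p of 0.769 with an estimated correlation and no block). The count of called genes was 0 with the array lot or the hybridisation day as a term, within the larger lot and within the first day.

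**Figure D2:**
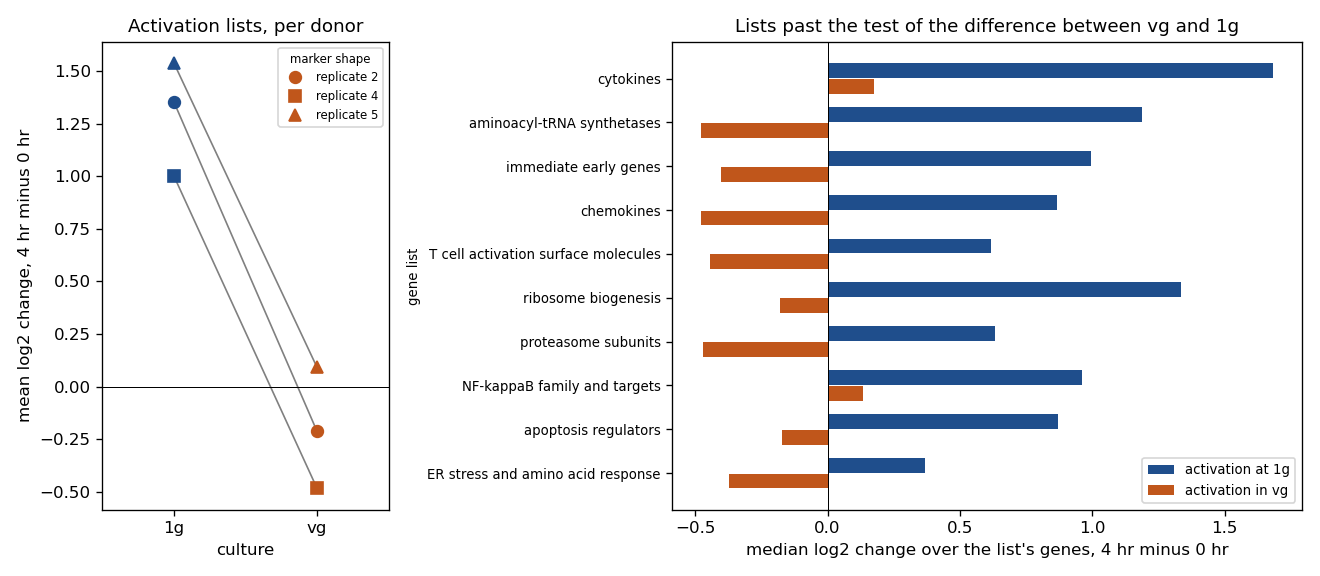
Left, mean log2 change from 0 to 4 hr over the 92 genes of the activation lists, for each donor (marker shapes), at 1g and in vg. Right, median log2 change over the genes of each list that passed the test of the difference, at 1g (blue) and in vg (orange), with no error shown. The difference between vg and 1g was -1.57, -1.49 and -1.45 in donors 2, 4 and 5, and at 4 hr alone it was -1.655, -0.898 and -1.299.

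The comparisons share groups, so their overlap was set against simulated data with no effect. Of the genes higher by activation at 1g, 10 were lower in vg at 4 hr. The simulation gave 0, but data with no effect in any group leave almost no gene to overlap. Independent lists would give 0.054, which ignores the shared arrays. Neither value can therefore tell how far the sharing of arrays made this overlap. Across genes, which are not independent replicates, the changes by activation at 1g and by vg at 4 hr had r = -0.55 against -0.50 in the simulation, and a covariance of -0.41 against -0.24. Both comparisons use the 1g 4 hr arrays. Activation at 1g and in vg had r = 0.07 across genes, against 0.00 in the simulation.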

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

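The list test and the regroupings for the number of lists and the share of genes in the difference of the response were set beforehand, and the other tests in this part (brightness, RNA quality, array lot, T cell share, single donors, fluidics module, probe sets left out, and the remaining regroupings, with those that keep donors paired in the difference of the response) were chosen after the results they bear on were seen.

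A difference between the groups, tested directly, brought out 10 gene lists whose activation response was lower in vg than at 1g at the preset correlation. With an estimated correlation cytokines alone passed (adjusted p = 0.0279), and the other 9 had an adjusted p from 0.0639 to 0.732 with an estimated correlation. The median differences in log2 were -1.35 for cytokines, -1.76 for aminoacyl-tRNA synthetases, -1.32 for immediate early genes, -1.50 for chemokines, -1.37 for T cell activation surface molecules, -1.80 for ribosome biogenesis, -1.02 for proteasome subunits, -1.12 for NF-kappaB family and targets, -1.02 for apoptosis regulators and -0.93 for endoplasmic reticulum stress and amino acid response. Regrouping the arrays between vg and 1g within each time point gave as many lists in 11 of 100 drawn splits, the real one included, with up to 15 lists in another split against 10 in the real one (adjusted within the comparison), so chance cannot be excluded for the number of lists. These regroupings ignored the donors. Of the 32 that keep 1 array of each donor in each group, 6 gave as many lists, with a highest other of 12. All 6 of these, and 9 of the 11, kept the real grouping at 4 hr and so its difference between vg and 1g, and the highest paired regrouping that did not keep it gave 6 lists. The activation lists' difference (-1.499) was as large in either direction in 2 of the 32 paired regroupings, the real one included. The other gave 1.559 and also kept the grouping at 4 hr. For genes, all 100 splits gave at least the 0 of the real one (limma, with 376 genes at an unadjusted p under 0.05), with a highest of 4 elsewhere. The share of 80% of responsive genes with a smaller response was matched or exceeded, in either direction, in 18 of the 20 drawn splits that had a responsive gene, with a highest of 100. In 11 of these 18 a single gene was responsive, which fixes the share at 0 or 100, and of the 9 splits with more, 7 matched it, so the share from so few genes decides nothing.

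The vg 4 hr arrays were dim, and random lists of like mean signal over all arrays also fell in vg at 4 hr, with a median of -0.30. Of 10000 such lists, 0% were as low as the activation lists (-1.28 against a lowest of -0.65). Their genes were unrelated, which narrows the spread of their means, so the 0% alone decides little. With brightness as a term the difference of the response was -1.31 against -1.50, which argues against dimness as the whole cause of this smaller response. The GAPDH gap was smaller in 1g 4 hr (0.63 ± 0.34) than in vg 4 hr (1.17 ± 0.41), but with it as a term, which moved 512 genes by over 0.5, the difference was -1.53 (SE 0.37), which argues against RNA quality as the whole cause for the lists, and of the 21 genes called in vg at 4 hr all 21 kept their direction, while the 18 that lost the call went from a median of -3.06 (median SE 0.59) to -2.96 (0.64). In the donors whose 4 arrays came from 1 lot the difference was -1.47, which argues against the array lot. The T cell receptor list was taken as a measure of the T cell share. The activation lists lay below it by -1.24 ± 0.16 (SD, n = 3 donors) in the difference of the response, where a share lower at both times would cancel. At 4 hr alone the gap was -0.77 ± 0.46, with -0.283 in donor 4. The T cell receptor list was itself at -0.822, -0.615 and -0.110 there, so a lower T cell share stays open as a part. Natural killer cell markers were also lower at 4 hr (-0.892, -1.702 and -0.751), and the share of such cells was not tested. The effect of vg on activation that the design names stays open as a hypothesis, as do the 2 hours of culture on the machine before activation and any loss of cell viability, none of which could be separated here. The fluidics module also differed between the groups of each donor, and its part was not tested.

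The second pattern was the immediate early and CREB lists, higher in vg at 0 hr at the preset correlation (adjusted p = 0.769 each with an estimated correlation). It lay in 1 donor: without vg 0 hr replicate 4 the median over both lists was 0.042 against 0.473. The immediate early genes are also part of the activation lists, so their higher values at 0 hr add to the difference of the response above. The lot differed between vg and 1g in donor 2 alone, whose shift was -0.06 against a mean of 0.47 ± 0.78 over the 3 donors, which argues against the array lot. The 3 vg 0 hr arrays were also the only ones on their fluidics module, and their culture on the machine cannot be told apart from it. No biological explanation was tested beyond the group itself.

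A signal also lay in probe sets with several gene names or none, which the comparisons did not use. Of 677 such probe sets, 2 were higher with activation at 1g and 2 were lower in vg at 4 hr (limma adjusted p under 0.05 when fitted with all genes).

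The splits of the 6 arrays in a pair of groups number 10 with the real one, too few for a share under 0.05. For activation at 1g the real split gave 15 genes and the highest other 2, and for vg at 4 hr it gave 21 and the highest other 1, and in both comparisons 1 split gave as many, the real one. For activation in vg the real split gave 0 genes (limma, with 430 at an unadjusted p under 0.05), so all 10 gave as many, and the highest other gave 15. That split parted the 3 dimmest of the 6 arrays from the 3 brightest, but the splits that part dim from bright arrays in the other comparisons gave 2 genes (activation at 1g), 0 (vg at 0 hr) and 1 (vg at 4 hr). A structure among the vg arrays is thus open, and was not tested further. With brightness as a term the real count stayed 0. For vg at 0 hr the real split gave 0 (117 at an unadjusted p under 0.05), all 10 gave as many, and the highest other gave 1. The lists past the preset test numbered 13 at activation at 1g with a highest other of 11 (1 split as large), 2 and 8 for activation in vg (5 splits), 3 and 8 for vg at 0 hr (8 splits), and 11 and 9 for vg at 4 hr (1 split), adjusted within each comparison. Among the 4 splits that part every donor's pair of arrays, the highest other count of genes was 0 in each of these comparisons. Each pair of groups holds unequal numbers of arrays from the 2 hybridisation days. A split of 3 against 3 could therefore not follow the day, and the splits do not test it.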

How the results depend on the processing

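The brightness term, the GAPDH gap term, the array quality weights and the fit without the 2 dimmest arrays outside vg 4 hr were chosen after seeing the data, and the other settings beforehand. Counts below are genes past the threshold, against 15 for activation at 1g, 0 for activation in vg, 0 for vg at 0 hr, 21 for vg at 4 hr and 0 for the difference of the response (limma), with a response difference of -1.499 for the activation lists and a share of 80%. The count for vg at 0 hr stayed 0 in every setting run, and the activation lists' difference stayed below 0. Vg at 4 hr gave 7 with quantile normalization, 8 with no filter, 34 (7 higher, 27 lower) with a 4 times higher floor, 53 with the replicate block, 13 (1 higher) with the array lot as a term, 8 with the block and lot, 3 in the larger lot only, 49 with the hybridisation day as a term, 5 with only the groups compared, 12 with brightness as a term, 3 with the GAPDH gap as a term, 69 with array quality weights, 69 with the block and weights and 10 without the dimmest arrays. Activation at 1g gave 24 (22 higher) with the block and lot, 5 in the larger lot only, 9 with only the groups compared, 5 with the GAPDH gap as a term, 36 (28 higher) with weights, 86 (63 higher) with the block and weights and 9 without the dimmest arrays. Activation in vg gave 1 with the 60th percentile filter, the block, the block and lot, the day term, and the block and weights, and 2 with the higher floor. The difference of the response gave 4 with the higher floor, 3 with weights and 12 with the block and weights. The lists' difference was -1.227 with quantile normalization, -1.404 with the median of kept probe sets, -1.4 with no filter, -1.603 with the 60th percentile filter, -1.236 with the higher and -1.594 with the lower floor. The share was 100% with either floor, no variance trend, or brightness as a term, with 1 to 3 responsive genes. With the block and weights, 28 of 58 responsive genes had the smaller response in vg (48.3%), so the share depends on the fit. With the GAPDH gap the median SE rose from 0.679 to 0.801 for activation at 1g and to 0.741 for vg at 4 hr. The larger lot, the groups compared and the fit without the dimmest arrays have fewer arrays. The cause of the other changes was not tested.

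Leaving out a donor or an array gave 1 to 16 genes for activation at 1g, 0 to 2 in vg, 0 to 122 for vg at 4 hr, 0 to 1 for the difference and 75% to 100% for the share. No responsive gene, and so no share, was left with no filter, the 60th percentile filter, the larger lot only, the GAPDH gap as a term, without the dimmest arrays and in some fits without a donor or an array. The share and the difference were not run with only the groups compared, nor lists with a fold minimum. The replicate block changed no call other than those given in the report and those behind its counts (15 against 19 for activation at 1g). Of the 951 values of called genes under other settings, 649 kept their call, 302 lost it and 0 changed sign. Of 5901 values of genes named as not past, 190 passed and 92 changed sign without passing in either fit (20 gene results, from -1.077 to 1.671). Of the 38 list calls, 22 passed in every other setting run, 16 lost the call in at least 1 and 0 turned. Those lost most often were endoplasmic reticulum stress and amino acid response (16 of 33 settings) and apoptosis regulators (12) in the difference of the response, immediate early genes (11 of 34) and apoptosis regulators (9) in vg at 4 hr, cytoskeleton and adhesion (10) in vg at 0 hr and CREB targets (9) for activation at 1g. The arrays were dim, with 9.2% of values at the floor after the filter, which limits what can be said of weak transcripts. Arrays of the same group correlated at 0.633 to 0.828 (median 0.77) over the genes tested. Arrays of different groups had a median of 0.736 and a highest of 0.85, so spread between arrays limits every comparison.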

Other observations

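The tests in this part were chosen after the values were seen.

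Metallothioneins, small proteins that bind zinc and copper and are induced by metals and stress, were mostly higher in vg, a pattern picked out after the values were seen. In vg at 0 hr, MT1X was at log2 2.75 (SE 1.04), MT1H at 2.55 (1.09), MT3 at 2.24 (0.89), MT2A at 1.83 (0.86) and MT1G at 0.14 (0.77). In vg at 4 hr, MT2A was at 2.58 (0.86), MT1X at 2.57 (1.04), MT1G at 2.41 (0.77), MT1H at 1.37 (1.09) and MT3 at -0.26 (0.89). No member passed in limma's test over all genes (adjusted p from 0.177 to 0.938 at 4 hr and 1 at 0 hr). The mean of the 5 genes over both times was higher in vg in all 3 donors, by 0.37, 4.35 and 0.73 in donors 2, 4 and 5 (two-sided exact sign-flip p = 0.25, the smallest that 3 donors allow), so most of the size came from donor 4. Heat shock genes in the same data were at 1.54 (HSPA6) and 1.05 (DNAJB1) at 0 hr and 1.82 and 2.04 at 4 hr, none past the test, and were picked for being high. The list of heat shock proteins and chaperones did not move with them: 9 of 16 were below 0 at 0 hr (median -0.16, camera adjusted p = 0.855) and 10 of 16 at 4 hr (median -0.29, adjusted p = 0.803).

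A hypothesis is that the machine's vessels or handling raised metallothioneins by stress or metal, but this was not tested. The lot differed between vg and 1g in donor 2 alone, whose shift was 0.37 against 4.35 and 0.73 in the donors of 1 lot, which argues against the array lot. Metallothionein sequences are alike, and probe sets may read each other's transcripts: deviations of MT1X and MT2A from their group means correlated at r = 0.96 over 12 arrays (permutation p = 2e-05, rho = 0.94, and r = 0.92 without the 2 arrays farthest from the median of MT1X, 1 relation tested), which co-regulation would give too, so the members do not count as separate evidence.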
